A study of Homo sapiens with 18 samples.

How the data were processed

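Total RNA from 3 human urothelial cancer cell lines was measured on Illumina bead arrays, with 18 arrays in 6 groups of 3. UC14 cells carried an shRNA against p63 or a non-targeting shRNA, Scaber cells an siRNA against STAT3 or a non-targeting siRNA, and UC7 cells were treated with 1 µM rosiglitazone for 24 h or left as controls. Per the labels, RNA was extracted with the mirVana kit, checked on a NanoDrop and a Bioanalyzer, and amplified to biotinylated cRNA with an Illumina kit. The lines came from a bladder cancer tissue bank and grew in MEM with serum, per the labels.

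Per the file headers, the authors exported the signal of 47323 probes on each array from GenomeStudio, whose version is not given in the sources used here. These deposited values are non-normalized signal intensities on the linear scale, and each comes with a deposited detection p-value that compares the probe with the negative controls of its own array. The authors also deposited log2 values that are quantile normalized over the 18 arrays. The submitters' processing notes name limma without a version. The sorted log2 values of the first array were checked against the log2 of the sorted raw signals averaged over the arrays. They differed by at most 0.00176, and the median log2 value was 6.48 on each of the 18 arrays. The deposited values thus show no sign of background subtraction, though they were not compared probe by probe.

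The raw signals and detection p-values were processed with limma 3.58.1 in R 4.3.3. The function neqc estimated the background of each array by normexp with detection p-values in place of negative control probes, added an offset of 16, quantile normalized the 18 arrays together and took log2. Probes were named through the platform annotation, which gave 1 gene symbol for 30113 probes. The 17202 probes that it does not list and the 8 with several symbols were left out of the gene tables. Gene identifiers were matched to RefSeq for 30074 probes and no symbol changed. A named probe was kept when its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 16221 probes. Each gene was represented by the probe with the highest mean log2 value over the 18 arrays, so 11978 genes were tested, and 3338 of them had further kept probes. Of 393 genes in the lists described here, 363 had a named probe and 300 were tested. The target of the p63 shRNA, TP63, was not analysed here, since no probe carried its name, and its knockdown was therefore not checked on the arrays.

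A linear model with a mean for each of the 6 groups was fitted to all 18 arrays with lmFit, and the 3 comparisons were taken as treated minus control within a line. Spread was moderated with eBayes (12 residual degrees of freedom and 4.29 prior degrees of freedom). P-values were two-sided and adjusted over all genes by Benjamini-Hochberg, with an adjusted p under 0.05 as the threshold. Errors beside a log2 change are standard errors from this fit with 3 arrays per group. A single spread per gene was pooled over all 18 arrays, so a gene has the same standard error in each comparison. This error is not the spread of the arrays compared. Array weights, lower for noisier arrays, were 0.372 to 0.816 in UC14 and 1.07 to 2.48 in UC7. Errors and p-values may thus be too small in UC14 and too large in UC7, which also bears on the counts of genes called. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision, and no depth applies to them.

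For a gene that was undetected (detection p of 0.01 or more) on all 3 arrays of 1 group, the change is given as a lower bound. The bound sets the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among detected probes and the probe's own signal. These bounds were calculated from the background-corrected values alone. No fold change is given where both groups were undetected.

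Before the data were examined, 20 gene lists were fixed: basal urothelial markers, luminal urothelial markers, p63 targets, hemidesmosome and basement membrane, squamous differentiation, STAT3 targets, PPAR targets, mitochondrial fatty acid oxidation, cholesterol synthesis, interferon response, inflammatory cytokines and NF-kB, cell cycle, p53 targets, mesenchymal markers, epithelial junction, unfolded protein and amino acid stress, hypoxia and glycolysis, EGFR family and ligands, stromal and smooth muscle markers, and immune and endothelial markers. The groups, comparisons, tests, alternatives and the rule for named genes were fixed at the same time. Each list was tested within a comparison with camera from limma, which sets its genes against all other genes, with a preset correlation between genes of 0.01 and adjustment over the 20 lists. A second camera test used a correlation estimated from the data. The members that passed the threshold were counted as higher or lower, with p-values adjusted over all genes and adjusted over the list alone. Differences of the basal and luminal lists between comparisons were tested with camera on the difference of the contrasts, adjusted over the 6 tests. Overlap between comparisons was set against the product of the shares called in each, without a p-value, also under an alternative that moved the counts. This product assumes that calls are independent between comparisons, which the pooled spread of each gene does not ensure.

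Named genes were STAT3 and PPARG, the 10 highest and 10 lowest changes past the threshold whose treated and control arrays did not overlap, up to 5 members of each list with the largest changes past the threshold, and any member of the basal and luminal lists and of the list of the comparison's own target. Other list members, named because a small count rested on them or because they stand beside a gene of another comparison, and the genes shared between comparisons were chosen after their values were seen.

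The procedure was tested on simulated data with the layout of these arrays. Noise was drawn independently for each gene, with its pooled spread, which was the same on every array. The simulations therefore cannot check how the pooled spread deals with arrays of unequal noise. Nor can they check how camera deals with correlated genes in a list. Added changes of 2 on the log2 scale were recovered at 100% in each comparison, changes of 1 at 89.6% to 92.5%, and changes of 0.5 at 37.9% to 45.5%. False calls made up 3.05% to 8.98% of all calls in these simulations. A list shifted on purpose was found in all 3 comparisons, and of the 19 lists left unshifted 1 was called in the UC14 simulation and 0 in the others.

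The alternatives tried were quantile normalization without background correction, median scaling in place of quantile normalization, the authors' log2 values, no detection filter, a detection p under 0.05, the 6 arrays of a comparison alone, the mean of a gene's probes, eBayes with trend and robust settings, array weights, the replicate number as a block, for UC7 the letter at the end of the title as a block, the estimated correlation in camera, and leaving out each array in turn. No array was left out of the reported values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.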

Results

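Gene expression was measured in 3 human urothelial cancer cell lines, each under a different intervention with its own control, on 18 arrays in 6 groups of 3. In UC14 the transcription factor p63, a regulator of basal and stratified epithelia, was knocked down with an shRNA. In Scaber, a line known to derive from a squamous carcinoma of the bladder, STAT3, a transcription factor downstream of cytokine receptors, was knocked down with an siRNA. UC7 was treated with 1 µM rosiglitazone, an agonist of the nuclear receptor PPARγ, for 24 h. The comparisons ask which genes lie downstream of each of these factors. Median signal per array was 98.5 to 114 in UC14, 96.3 to 115.9 in Scaber and 51.6 to 56.3 in UC7. Between 14032 and 15432 probes were detected per array in UC14, 16473 to 18021 in Scaber and 19093 to 20440 in UC7. Correlation between arrays of a group was 0.982 to 0.997, and between the 2 groups of a line 0.945 to 0.980.

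In UC14 under p63 shRNA, the basal keratins KRT5 and KRT6C were lower and the uroplakins UPK2, UPK1A, UPK3B and UPK1B were higher. KRT5, the keratin of basal urothelium, was at least 15.9-fold lower and was not detected on any p63 shRNA array, while UPK2, a membrane protein of differentiated urothelium, was at least 21.2-fold higher and was not detected on any control array. PSCA, a surface antigen of urothelial and prostate cells, rose 90.9-fold (log2 change 6.51 ± 0.22), and LCN2, an iron-carrier-binding protein, rose by 5.68 ± 0.13. The cytokine IL1A fell by 4.41 ± 0.14 on the log2 scale. Interferon-induced genes rose together, and genes of cholesterol synthesis and of the hypoxia response fell.

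Of 8 basal markers tested, 5 fell, 0 rose and 3 did not pass, with 5 and 0 when adjusted over the list alone. KRT6C was at least 5.56-fold lower, the cadherin CDH3 fell by 1.34 ± 0.10, and the hyaluronan receptor CD44 fell by 0.74 ± 0.08. DSC3, a desmosomal cadherin detected on 3 control and 1 p63 shRNA arrays, changed by -1.31 ± 0.12. KRT16 differed by 0.29 (adjusted p = 0.172), while its other kept probe differed in sign or call, and KRT14 and DSG3 were undetected in both groups. The list was shifted down (median log2 change -1.03, or -1.32 with undetected members at their bound; camera adjusted p = 0.000293), with adjusted p = 0.0864 with an estimated correlation.

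Of 19 luminal markers, 13 rose, 2 fell and 4 did not pass, with 13 and 3 adjusted over the list alone. UPK1A was at least 6.25-fold higher, the transcription factor ELF3 rose by 1.57 ± 0.10, the receptor ERBB3 by 1.46 ± 0.10 and KRT8 by 1.34 ± 0.10. UPK3B rose by 1.26, UPK1B by 1.16, ERBB2 by 1.04, and the luminal regulators FOXA1 and GATA3 by 0.65 and 0.47. The 2 that fell, FGFR3 and CYP2J2, changed by -0.46 and -0.35, and under median scaling by -0.30 and -0.21 without passing the threshold. The list rose (median 0.648, or 0.845 with undetected members at their bound; adjusted p = 6.05e-05), with adjusted p = 0.0554 with an estimated correlation.

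Of 16 known p63 targets, 13 fell, 1 rose and 2 did not pass, with 14 and 1 adjusted over the list alone. HAS3, a hyaluronan synthase, fell by 3.22 ± 0.09 (by 1.86 with the mean of its probes), the transcription factor SNAI2 by 2.43 ± 0.14, S100A2 by 2.18 ± 0.10, the Notch ligand JAG1 by 1.98 ± 0.11 and hexokinase HK2 by 1.79 ± 0.10. TFAP2C was the member that rose, by 1.09 ± 0.08. The list fell (median -1.09, or -0.90 with undetected members at their bound; adjusted p = 2.75e-08). The TP63 transcript itself was not analysed here. STAT3 and PPARG differed by -0.18 (adjusted p = 0.228) and 0.08 (adjusted p = 0.461) in UC14, and 1 of the 3 STAT3 probes, at -0.39, passed the threshold. Another kept PPARG probe, at 0.35, did not pass.

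**Figure D1:**
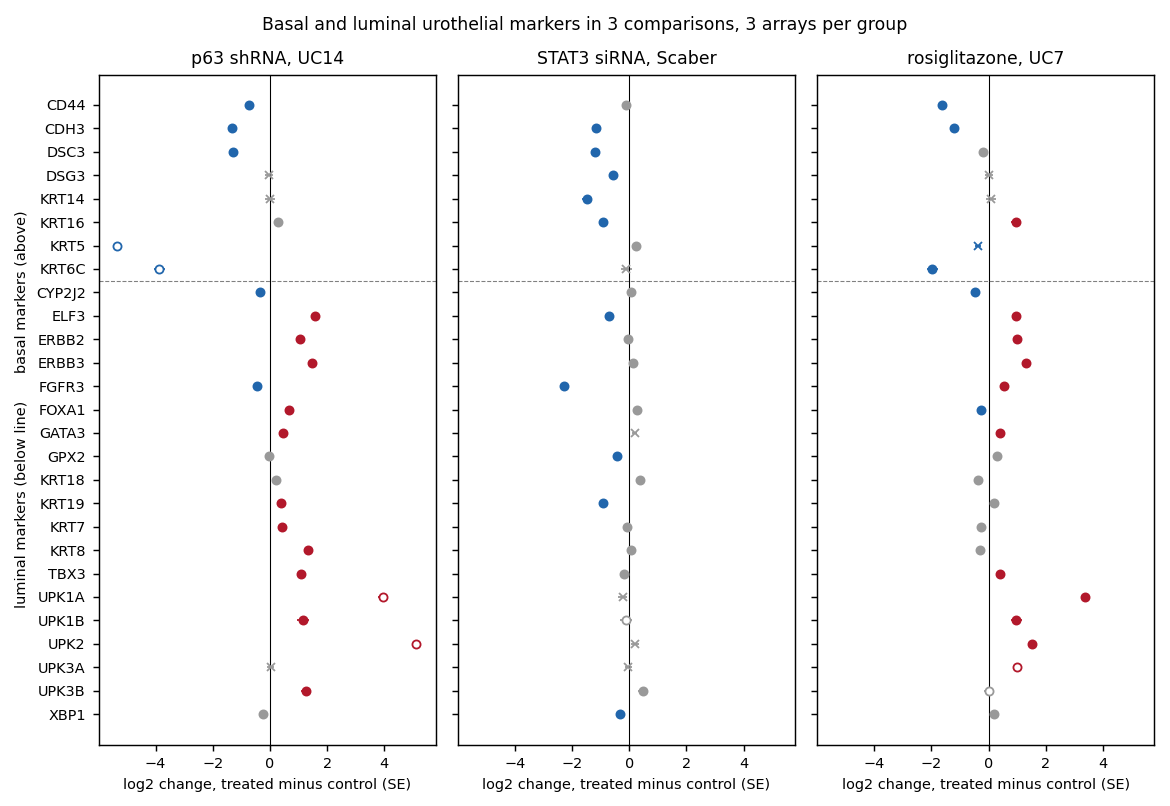
Log2 change (treated minus control, x axis, bars are standard errors, 3 arrays per group) of each basal and luminal marker tested, in the 3 comparisons; filled circles are genes detected in both groups, open circles genes undetected on all arrays of 1 group, crosses genes undetected in both, and red, blue and grey mark higher, lower and not past the threshold. The bars use the spread pooled over all 18 arrays, so a gene has the same bar in each comparison. KRT5 lies farthest left and UPK2 farthest right in UC14, where 13 of 19 luminal markers rose, while 0 rose in Scaber and 10 rose in UC7.

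Of 30 interferon response genes in UC14, 22 rose, 0 fell and 8 did not pass, with 23 and 0 adjusted over the list alone. The antiviral protein IFIT2 rose by 2.28 ± 0.12, and IFI27, undetected in the controls, was at least 1.96-fold higher. The antiviral GTPase MX1 and the RNA sensor IFIH1, each detected on 2 control arrays, rose by 2.23 ± 0.25 and 2.21 ± 0.17. The list's median was 1.44, or 0.968 with 6 undetected members at their bound (adjusted p = 4.98e-11), and it was 0.895 without background correction and 0.812 with the authors' values. Of 16 cholesterol synthesis genes 11 fell, 1 (HSD17B7, by 0.82) rose and 4 did not pass, the same counts as adjusted over the list alone (adjusted p = 0.000503). SQLE, an early enzyme of the sterol branch, fell by 1.18 ± 0.11 and MVK and FDPS by 1.07 and 1.04. Of 15 hypoxia and glycolysis genes 11 fell and 0 rose, with 12 and 0 adjusted over the list alone (adjusted p = 6.05e-05), among them NDRG1 (-1.25), the glycolytic regulator PFKFB4 (-1.12) and the mitophagy receptor BNIP3 (-0.76). Of 16 unfolded protein and amino acid stress genes 8 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.00744), including TRIB3 (-1.54), DDIT4 (-1.20) and the serine synthesis enzyme PSAT1 (-0.78). Of 13 epithelial junction genes 8 rose and 0 fell, with 8 and 1 adjusted over the list alone (adjusted p = 0.0166), led by the claudins CLDN7 (2.40) and CLDN1 (1.86).

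Among 18 inflammatory genes in UC14, 5 fell, 1 rose and 12 did not pass, and 10 members were undetected in both groups. IL1A, the prostaglandin synthase PTGS2 (-3.48 ± 0.18) and IL1B (-3.15 ± 0.12, detected on 2 p63 shRNA arrays) fell, and TNFAIP2 rose by 1.34. The list's camera adjusted p was 0.0476 (0.0772 with an estimated correlation), and it ranged up to 0.0838 over the alternatives, where 6 of 11 ended the call, and was 0.0664, 0.0547 and 0.0555 without non-targeting replicate 3, p63 shRNA replicate 2 and p63 shRNA replicate 3. Of 29 cell cycle genes 12 fell, 3 rose and 14 did not pass. CCNA2 fell by 0.77, BUB1 by 0.71 and BIRC5 by 0.70, while the proliferation antigen MKI67 rose by 0.86. This list's adjusted p was 0.039 (0.156 with an estimated correlation), 0.0997 under median scaling, 0.0576 with the mean of a gene's probes, and 0.0743 and 0.0555 without p63 shRNA replicates 1 and 3. For both lists the counts adjusted over the list alone were the same.

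The other 10 lists did not pass in UC14. Of 13 hemidesmosome genes 5 fell and 3 rose (adjusted p = 0.223), with ITGA6 at -1.62 ± 0.11, FRAS1 at -1.26 and LAMB3 at 1.10. Of 15 squamous differentiation genes 6 rose and 2 fell (0.512), with SPRR3 at 2.68 and the calprotectin subunits S100A8 and S100A9 at -1.72 and -1.37. Of 22 STAT3 targets 8 rose and 6 fell (0.455), with LCN2 and MUC1 (3.96) up and MYC (-0.93) down. Of 19 PPAR targets 7 rose and 3 fell (0.256), with the mitochondrial carrier UCP2 at least 15.3-fold higher and the fatty acid carrier FABP4 at -2.18 ± 0.17. Of 18 fatty acid oxidation genes 7 rose and 1, HADHA at -0.34, fell (0.0757, or 0.0152 without the detection filter). Of 17 p53 targets 4 rose and 2 fell (0.893), with GDF15 at 2.23 and CCNG1 at -0.83. Of 11 mesenchymal markers 4 fell and 2 rose (0.0757), with TGFBI at -2.33 and S100A4 at 3.16. That p was 0.0204 under median scaling, 0.0461 with array weights, 0.050 with the 6 arrays alone and 0.0493 without non-targeting replicate 1. Of 7 EGFR family genes 3 rose and 3 fell (0.73), with the ligand HBEGF at -2.85 ± 0.10. Of 4 stromal markers 0 rose and 1 was called lower (0.772), ACTG2, which was detected on 1 control array and 0 p63 shRNA arrays and whose groups overlapped. Of 5 immune and endothelial markers 2 rose and 0 fell (0.455), CD68 at 1.26 and PECAM1, detected on 1 control array, at 0.87 (0.57 and no call with the 6 arrays alone, and no call without non-targeting replicates 2 or 3 or p63 shRNA replicate 2, at 0.85, 0.49 and 0.71). Adjusted over the list alone, higher and lower counts were 9 and 6 for the STAT3 targets, 8 and 1 for fatty acid oxidation, 2 and 5 for the mesenchymal markers, and as stated for the other 7 lists. Median and mean had opposite signs for the STAT3 targets (-0.01 and 0.44), p53 targets (-0.02 and 0.08), stromal (0.05 and -0.21) and immune markers (-0.03 and 0.37), and the test followed the mean.

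Outside the lists, SH3PXD2A, a scaffold protein of podosomes, was at least 10.98-fold lower, the fructose carrier SLC2A5 at least 8.30-fold and APCDD1L at least 6.86-fold lower. The chemokine receptor ACKR3 fell by 3.59 ± 0.12, and CDK6, a G1 kinase detected on 2 p63 shRNA arrays, by 3.51 ± 0.11. APOD was at least 10.3-fold and TLE6 at least 10.0-fold higher. HPGD, the enzyme that inactivates prostaglandins, rose by 4.80 ± 0.14 and VSIG2 by 4.79 ± 0.19, with 1 control array detected for each. In all, 5351 of 11978 genes passed the threshold in limma, 2845 higher and 2506 lower, and 1080 changed at least 2-fold (716 higher and 364 lower). Of the genes called in UC14, 179 were undetected in both groups. Under median scaling, which moved the median change of all genes to 0.10, 3211 were higher and 1262 lower, and the number changed at least 2-fold was 493 without background correction and 482 with the authors' values, where dim genes such as MX1 (1.33 in both) changed less. In both of these, KRT5, KRT6C, UPK2, UPK1A, UCP2, SH3PXD2A, SLC2A5, APCDD1L, APOD and TLE6 changed by less than the bounds stated for them, which hold for background-corrected values.

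In Scaber, STAT3 mRNA was 9.61-fold lower under its siRNA (log2 change -3.26 ± 0.11, adjusted p = 4.93e-12; mean log2 signal 9.90 in controls and 6.64 after knockdown), and another of its 3 probes changed by -2.77. The remaining probe was detected on 3 control arrays and 0 siRNA arrays. Genes of DNA replication and mitosis fell as a group, as did known STAT3 targets and genes of the hypoxia response. Squamous differentiation genes and basal markers also fell, with adjusted p = 0.0745 and 0.192 with an estimated correlation. The imprinted non-coding RNA H19 fell 16.4-fold, with 1 of 3 siRNA arrays detected, and the serpin SERPINB4 fell 10.4-fold. The largest rise was that of CPA4, a carboxypeptidase, at 6.09-fold (2.61 ± 0.17).

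Of 29 cell cycle genes in Scaber, 26 fell, 0 rose and 3 did not pass, with 27 and 0 adjusted over the list alone. Thymidine kinase TK1 fell by 1.32 ± 0.10, thymidylate synthase TYMS by 1.17 ± 0.14, the replicative helicase subunit MCM2 by 1.15 ± 0.13 and topoisomerase TOP2A by 1.07 ± 0.10. The 3 that did not pass were MKI67 (-0.03), RRM2 (-0.35) and E2F1 (0.41). The list's median was -0.803 (adjusted p = 7.69e-20). Of 22 STAT3 targets 11 fell, 0 rose and 11 did not pass, with 11 and 2 adjusted over the list alone (adjusted p = 0.000404, median -0.428). The acute-phase protease inhibitor SERPINA3 fell by 1.88 ± 0.12, the repressor BCL6 by 1.65 ± 0.11, MUC1 by 1.61 ± 0.16, BCL3 by 1.32 ± 0.16 and SOCS3, the feedback inhibitor of cytokine signalling, by 1.22 ± 0.15. MYC (-0.04), MCL1 (0.06), LCN2 (0.15) and CCND1 (0.38) did not pass. Of 15 hypoxia and glycolysis genes 11 fell, 1 (ANKRD37, by 0.51) rose and 3 did not pass, with 11 and 2 adjusted over the list alone (adjusted p = 7.05e-06). BNIP3 fell by 1.58 ± 0.10, PFKFB4 by 1.32 ± 0.12 and the prolyl hydroxylase subunit P4HA1 by 1.14 ± 0.11.

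Of 8 basal markers in Scaber, 5 fell, 0 rose and 3 did not pass, with 5 and 1 adjusted over the list alone. KRT14 fell by 1.48 ± 0.17, DSC3 by 1.20 ± 0.12, CDH3 by 1.17 ± 0.10 and KRT16 by 0.90 ± 0.17, whereas KRT5 differed by 0.25 (adjusted p = 0.103). DSG3 changed by -0.56, and did not pass without non-targeting replicate 2 (-0.42) or STAT3 siRNA replicate 1 (-0.40). The list's adjusted p was 0.00139, and 0.192 with an estimated correlation. Of 15 squamous differentiation genes 7 fell, 1 (SPRR1A, by 0.49) rose and 7 did not pass, also adjusted over the list alone. S100A7, a psoriasin of keratinizing epithelium, fell by 2.47 ± 0.10, the crosslinking enzyme TGM1, detected on 2 siRNA arrays, by 1.94 ± 0.23, S100A8 by 1.82 ± 0.11 and S100A9 by 1.16 ± 0.11. This list's adjusted p was 0.00139, and 0.0745 with an estimated correlation. Of 30 interferon response genes 12 rose, 3 fell and 15 did not pass, with 15 and 4 adjusted over the list alone. OAS1, an antiviral nucleotide synthetase, rose by 1.29 ± 0.12, MX1 by 0.97 and CXCL10, detected on 2 control arrays, by 0.96, and OASL (-0.54), IFITM1 (-0.51) and HERC6 (-0.38) fell. The interferon list's adjusted p was 0.00605, and 0.291 with an estimated correlation.

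The other 14 lists did not pass in Scaber. Of 19 luminal markers 5 fell and 0 rose (adjusted p = 0.32), with the receptor FGFR3 at -2.30 ± 0.13, KRT19 at -0.91 and ELF3 at -0.70. UPK3B, at 0.49, did not pass (adjusted p = 0.0531), but only 1 of its 4 kept probes gave that sign and call. Of 16 p63 targets 5 fell and 1 rose (0.251), with JAG1 at -0.60. Of 13 hemidesmosome genes 3 fell and 1 rose (0.199), with ITGA6 at -0.72, COL7A1 at -0.68 and FRAS1 at 0.85. Of 19 PPAR targets 5 fell and 3 rose (0.367), with FABP4 at least 1.49-fold lower and LPIN1 at 0.67. Of 18 fatty acid oxidation genes 5 rose and 0 fell (0.0637), with ETFA at 0.59. That p was 0.0175 without the detection filter, and 0.0455 and 0.0418 without replicate 2 of the non-targeting and of the STAT3 siRNA. Of 16 cholesterol synthesis genes 4 rose and 2 fell (0.638), with SC5D at 0.68 and SQLE at -0.50. Of 18 inflammatory genes 6 fell and 3 rose (0.367), with PTGS2 at -1.38, CXCL8 at -1.04 and IL6 at 1.27 ± 0.18. Of 17 p53 targets 2 rose and 0 fell (0.638), GDF15 at 0.91 and GADD45A at 0.84. Of 11 mesenchymal markers 3 fell and 2 rose (0.656), with COL5A1 at -0.76 and TAGLN at 1.36. Of 13 junction genes 3 rose and 2 fell (0.274), with CLDN1 at -0.50. Of 16 unfolded protein genes 5 fell and 1 rose (0.366), with the chaperone DNAJB9 at -1.14. Of 7 EGFR family genes 2 fell and 1 rose (0.638), with TGFA at -0.62. Of 4 stromal markers 2 fell and 1, ACTG2, was at least 1.77-fold higher (0.673), and of 5 immune markers 2 fell and 0 rose (0.251), with CD14 at -1.13. Adjusted over the list alone, higher and lower counts were 3 and 5 for luminal markers, 2 and 5 for p63 targets, 1 and 4 for hemidesmosome genes, 4 and 2 for junction genes, 3 and 5 for unfolded protein genes, and as stated for the rest. For the mesenchymal markers the median (0.0813) and mean (0.0046) were positive and the test pointed down, and for the stromal markers the median (-0.18) and test were negative and the mean (0.21) positive.

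Outside the lists, the chloride channel regulator CLCA2 (-3.11 ± 0.10, detected on 2 siRNA arrays), the prostaglandin carrier SLCO2A1 (-2.82 ± 0.13), granulysin (GNLY, -2.66 ± 0.11) and the methyltransferase NNMT (-2.65 ± 0.08) fell. The protease ADAMTS1 rose by 2.12 ± 0.10, the small heat shock protein HSPB8 by 2.05 ± 0.13 and endothelin 1 (EDN1) by 1.77 ± 0.17. PPARG differed by -0.01 (adjusted p = 0.931). In all, 3106 genes passed in limma, 1451 higher and 1655 lower. Of the 318 that changed at least 2-fold, 56 were higher and 262 lower. Under median scaling 638 were higher and 1831 lower, and the number changed at least 2-fold was 113 without background correction and 120 with the authors' values, where FABP4 changed by less than its bound.

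**Figure D2:**
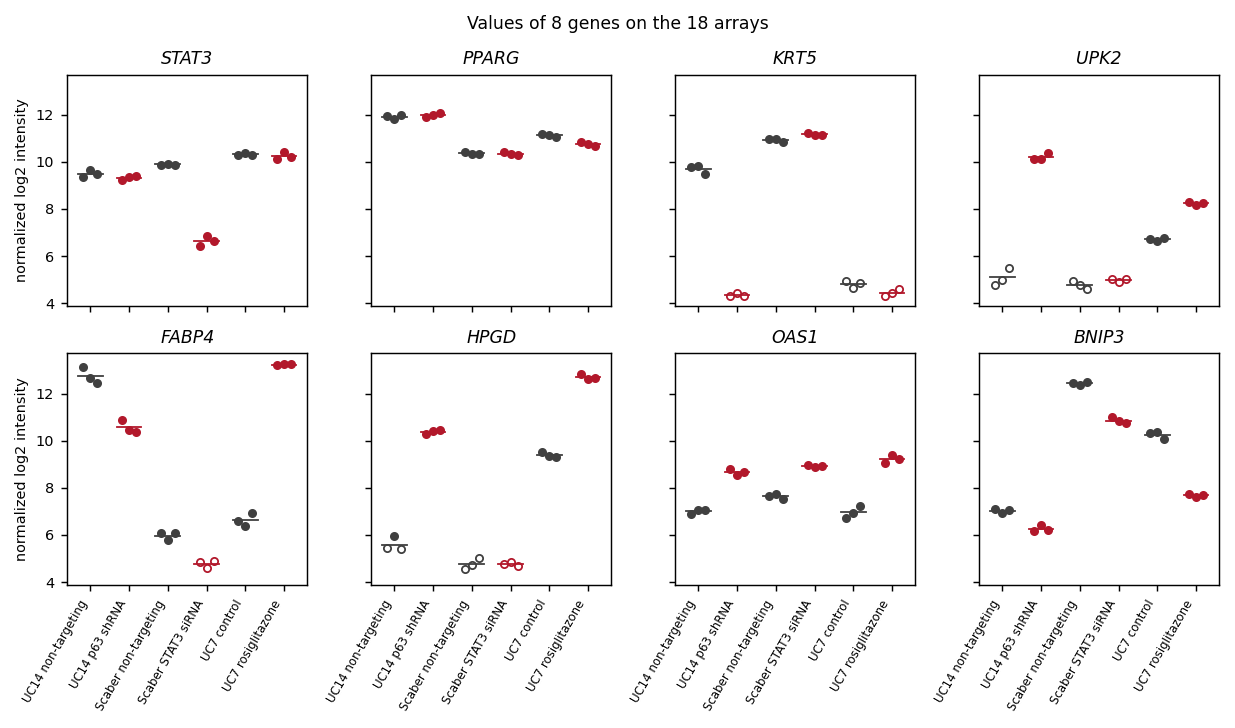
Normalized log2 signal (y axis) of 8 genes on each of the 18 arrays, by group (x axis); filled points are arrays on which the probe was detected, open points arrays on which it was not, and bars are group means. The STAT3 mean is 9.90 in Scaber controls and 6.64 under STAT3 siRNA, and FABP4 is 96.8-fold higher with rosiglitazone in UC7.

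In UC7, rosiglitazone raised FABP4, a fatty acid carrier and known PPARγ target, 96.8-fold (log2 change 6.60 ± 0.17), the largest change of any named gene in the 3 comparisons. Squamous differentiation genes, cholesterol synthesis genes and interferon-induced genes rose as groups, and genes of the hypoxia response fell. Luminal markers also rose and hemidesmosome and basement membrane genes fell, with adjusted p = 0.0752 and 0.0667 with an estimated correlation. Among single genes, the acyl-CoA synthetase ACSBG1 rose by 3.92 ± 0.20, the uroplakin UPK1A by 3.38 ± 0.15 and HPGD by 3.30 ± 0.14. Tissue factor (F3) fell 10.1-fold (-3.33 ± 0.13), and the ectonucleotidase NT5E (-3.11 ± 0.15) and the receptor kinase AXL (-2.82 ± 0.20) fell. PPARG mRNA fell by 0.37 ± 0.08 (adjusted p = 0.00249), another of its kept probes by 0.66, and the remaining one was detected on 3 control arrays and 0 rosiglitazone arrays. STAT3 differed by -0.08 (adjusted p = 0.692).

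Of 19 PPAR targets in UC7, 10 rose, 1 fell and 8 did not pass, also adjusted over the list alone. Besides FABP4, those that rose included UCP2 (5.66-fold higher), the fatty acid receptor CD36 (1.76 ± 0.09), the peroxisomal protein PEX11A (1.10 ± 0.17), the water and glycerol channel AQP3 (1.09 ± 0.24) and PDK4 (0.96 ± 0.12). Lipoprotein lipase (LPL) fell by 1.03 ± 0.18, while PLIN2 (-0.24) and CPT1A (-0.17) did not pass. The list's median was 0.393 (adjusted p = 6.14e-05). Of 18 fatty acid oxidation genes 8 rose, 1 fell and 9 did not pass, also adjusted over the list alone. HADH rose by 0.75 ± 0.08 and CPT2 by 0.71 ± 0.14, and ECI2 fell by 1.47 ± 0.11. This list's adjusted p was 0.0322, with 0.0752 with an estimated correlation, 0.094 under median scaling and 0.0504 without control replicate 3. Of 16 cholesterol synthesis genes 10 rose, 0 fell and 6 did not pass, with 11 and 0 adjusted over the list alone (adjusted p = 6.14e-05), led by HMGCS1 (0.86 ± 0.10), MVD (0.79 ± 0.12) and SQLE (0.69 ± 0.11).

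Of 19 luminal markers in UC7, 10 rose, 2 fell and 7 did not pass, with 10 and 4 adjusted over the list alone. Besides UPK1A, UPK2 rose by 1.53 ± 0.14, ERBB2 by 1.01 ± 0.11, UPK1B by 0.97 ± 0.20 and ELF3 by 0.96 ± 0.10, and UPK3A, undetected in the controls, was at least 1.66-fold higher. ERBB3 rose by 1.29 ± 0.10, with 2 of its 3 probes past the threshold (0.75 with their mean). The 2 that fell were CYP2J2 (-0.46) and FOXA1 (-0.27, adjusted p = 0.0489). FOXA1 no longer passed under median scaling (-0.30), without the detection filter, with a detection p under 0.05 or without any 1 of the 6 arrays (-0.24 to -0.31). The list's median was 0.396 (adjusted p = 0.000341), with adjusted p = 0.0752 with an estimated correlation. Of 8 basal markers 4 fell, 1 (KRT16, by 0.95, or 1.81 with the 6 arrays alone) rose and 3 did not pass, also adjusted over the list alone. CD44 fell by 1.63 ± 0.08, CDH3 by 1.22 ± 0.10 and KRT6C, detected on 2 rosiglitazone arrays, by 1.97 ± 0.19. KRT5, the remaining member called lower, was undetected in both groups. The basal list's adjusted p was 0.0132, and 0.208 with an estimated correlation.

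Of 15 squamous differentiation genes in UC7, 9 rose, 2 (DSC2 by -0.99 and SPRR2A by -0.94) fell and 4 did not pass, also adjusted over the list alone (adjusted p = 7.16e-06). S100A8 and S100A7 each rose by 3.26, S100A12 by 2.09 ± 0.11, S100A9 by 2.01 ± 0.11 and KRT13 by 1.97 ± 0.09. Of 30 interferon response genes 19 rose, 1 (CXCL10, by -0.42) fell and 10 did not pass, with 20 and 2 adjusted over the list alone (median 0.549, or 0.563 with undetected members at their bound; adjusted p = 4.12e-09). OAS1 rose by 2.26 ± 0.12, MX1 by 1.61 ± 0.25, UBE2L6, which conjugates ISG15, by 1.20 ± 0.14 and OAS3 by 1.03 ± 0.09. Of 15 hypoxia and glycolysis genes 12 fell, 0 rose and 3 did not pass, also adjusted over the list alone (adjusted p = 2.06e-07), among them BNIP3 (-2.56 ± 0.10), the peptide hormone ADM (-1.11 ± 0.14) and ANKRD37 (-0.74 ± 0.11).

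Of 13 hemidesmosome and basement membrane genes in UC7, 7 fell, 1 (the linker PLEC, by 0.99) rose and 5 did not pass, also adjusted over the list alone. The collagen chains COL4A6 and COL4A5 fell by 1.87 ± 0.09 and 1.16 ± 0.09, and the integrin activator FERMT1 by 1.08 ± 0.11. This list's adjusted p was 0.000355, and 0.0667 with an estimated correlation. Of 16 unfolded protein and amino acid stress genes 5 fell, 0 rose and 11 did not pass, also adjusted over the list alone. TRIB3 fell by 0.84, PPP1R15A by 0.80 and PSAT1 by 0.79. Its adjusted p was 0.0239, and 0.0693 with an estimated correlation. Of 11 mesenchymal markers 5 fell, 2 rose and 4 did not pass, also adjusted over the list alone. TGFBI fell by 2.31 ± 0.10, COL5A1 by 1.24 ± 0.15 and the transcription factor TWIST1 by 0.99 ± 0.23, while S100A4 rose by 1.46 ± 0.19 and ZEB2, detected on 2 control arrays, by 0.68. The mesenchymal list's adjusted p was 0.039, and 0.195 with an estimated correlation, 0.101 under median scaling, 0.0586 without the detection filter, 0.0692 with the 6 arrays alone and 0.0526 with array weights.

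The other 9 lists did not pass in UC7. Of 16 p63 targets 6 fell and 2 rose (adjusted p = 0.138), with SNAI2 at -2.72 ± 0.14, JAG1 at -1.25 and HAS3 at 1.97 ± 0.09. Of 22 STAT3 targets 6 rose and 6 fell (0.912), with BCL6 at 1.86, PIM1 at 1.16 and MYC at -1.69. Of 18 inflammatory genes 6 fell and 5 rose (0.213), with IL1A at -2.64, IL6 at -2.14, IL1B at -1.90 and TNFAIP2 at 1.97. Of 29 cell cycle genes 1, TK1 at -0.49, fell and 0 rose (0.61). Of 17 p53 targets 4 rose and 3 fell (0.727), with GADD45A at -1.47, TP53I3 at -1.17 and BAX at 1.94 on 1 of its 2 probes (0.98 with their mean). Of 13 junction genes 4 rose and 2 fell (0.726), with TJP1 at -0.59. Of 7 EGFR family genes 2 rose and 3 fell (0.61), with the ligands EREG at -0.92 and TGFA at -0.81. Of 4 stromal markers 1, COL1A2 at 0.78, rose and 0 fell (0.684), and COL1A2 did not pass without the detection filter (0.79), or without rosiglitazone replicates 1, 2 or 3 (0.71, 0.81 and 0.82) or control replicates 2 or 3 (0.77 and 0.69). Of 5 immune and endothelial markers 2 rose, PECAM1 at 1.74 and CD14 at 1.45, and 1 fell, CD68 at -0.41 (0.496), though CD68 did not pass without background correction (-0.24), with the 6 arrays alone (-0.06) or with the mean of its probes (-0.12). Adjusted over the list alone, higher and lower counts were 3 and 7 for p63 targets, 6 and 9 for inflammatory genes, 6 and 3 for p53 targets, 2 and 4 for the EGFR family, and as stated for the rest. For the STAT3 targets median and mean (0.00952 and 0.0163) were positive and the test pointed down, and for the junction genes the median was -0.00481 and the mean 0.0529, with the test pointing up.

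Outside the lists, HOPX, a homeodomain protein of differentiating epithelia, rose by 3.39 ± 0.09, the metalloproteinase inhibitor TIMP3 by 3.10 ± 0.12 and the phospholipase PLA2G2A, detected on 1 control array, by 2.92 ± 0.16. ANXA10 fell by 2.77 ± 0.13, the receptor kinase antagonist SPRY2 by 2.63 ± 0.16 and stanniocalcin 2 (STC2) by 2.61 ± 0.09. In all, 2934 genes passed in limma, 1492 higher and 1442 lower, and 500 changed at least 2-fold (268 higher and 232 lower). Under median scaling 1186 were higher and 1702 lower. The count past the threshold was 4591 with the 6 arrays of the comparison fitted alone and 4894 with array weights, and the number changed at least 2-fold was 249 without background correction and 255 with the authors' values, where UPK3A changed by less than its bound.

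**Figure D3:**
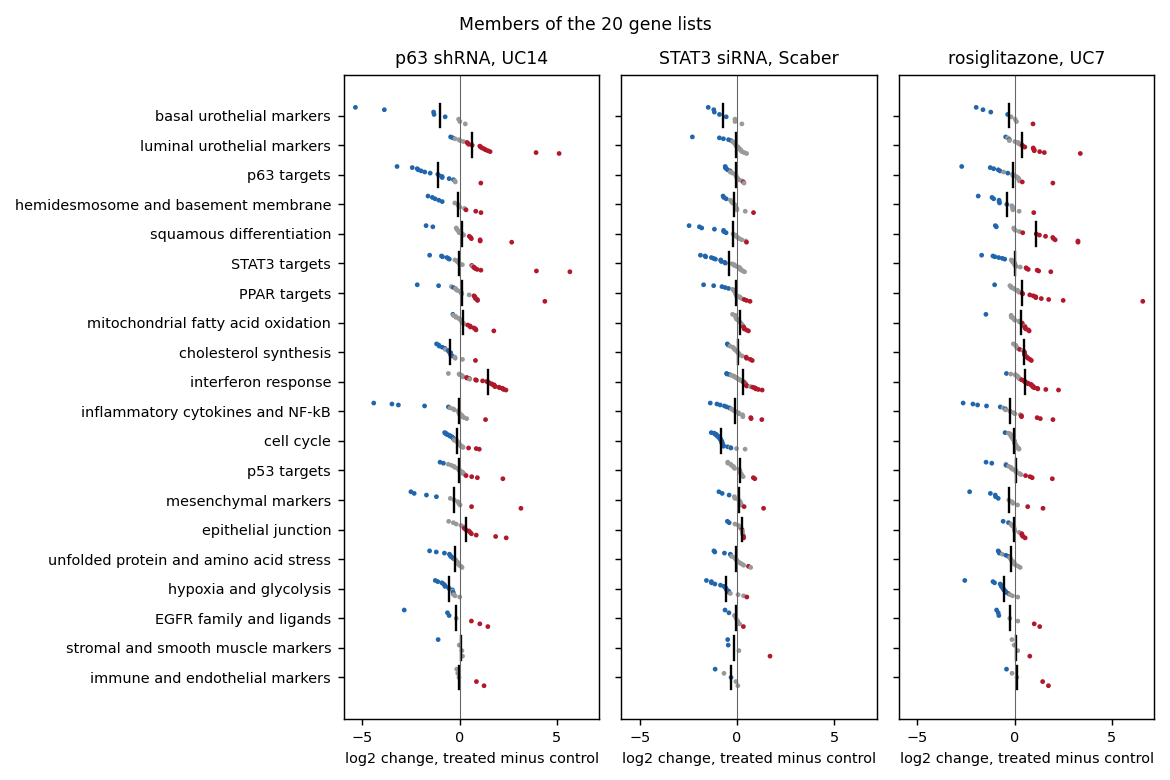
Log2 change (treated minus control, x axis) of every tested member (points) of the 20 gene lists (y axis) in the 3 comparisons, with black bars at the median of each list. The interferon response list lies to the right in all 3, with medians of 1.44, 0.32 and 0.549, and the hypoxia and glycolysis list to the left, with medians of -0.526, -0.562 and -0.568.

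Across the comparisons, the hypoxia and glycolysis list fell in all 3 lines. The interferon response list rose in all 3 with the preset correlation, and in Scaber it had adjusted p = 0.291 with an estimated correlation. The calls that hold with an estimated correlation are, in UC14, the p63 targets (adjusted p = 0.00157), interferon response (0.0183), and cholesterol synthesis, epithelial junction, unfolded protein and hypoxia lists (0.0466 each). In Scaber they are cell cycle (0.000156), STAT3 targets (0.00847) and hypoxia (0.0434), and in UC7 interferon response, squamous differentiation, PPAR targets and hypoxia (0.0178 each) and cholesterol synthesis (0.0222). In total 10 lists shifted in UC14, 6 in Scaber and 11 in UC7, and 6, 3 and 5 of these hold.

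The luminal list moved differently under p63 shRNA and STAT3 siRNA (median difference 1.10, adjusted p = 8.46e-06) and under STAT3 siRNA and rosiglitazone (median difference -0.72, adjusted p = 0.000396), with adjusted p = 0.0697 and 0.109 with an estimated correlation. Between p63 shRNA and rosiglitazone the luminal difference had adjusted p = 0.0438, with 0.306 with an estimated correlation, 0.128 under median scaling, and up to 0.0706 with 1 array left out, without p63 shRNA replicate 3. The basal list fell more under p63 shRNA than under rosiglitazone (adjusted p = 0.0295), with 0.306 with an estimated correlation and 0.0608 with the mean of a gene's probes. In UC7, however, 3 of the 8 basal markers, KRT5 among them, were undetected in both groups and had no measurable room to fall. In UC14, 2 were undetected in both groups, and KRT5 fell the most. The basal difference therefore does not show a weaker response to rosiglitazone. Basal differences between STAT3 siRNA and p63 shRNA (adjusted p = 0.161) and rosiglitazone (0.857) did not pass. Each intervention was made in its own line, so line and intervention cannot be separated in these differences.

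Changes under p63 shRNA in UC14 and under rosiglitazone in UC7 overlapped. Of the genes past the threshold in both, 1236 changed the same way, where 656.1 were expected from the counts, and 419 changed in opposite ways, where 654.7 were expected. Both higher were 759 (354.4 expected) and both lower 477 (301.7 expected). Across the 11978 genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.304 and Spearman rho = 0.257. At least 2-fold in both with background-corrected values, 88 genes rose and 60 fell. Those that rose included PSCA (6.51 in UC14 and 2.32 in UC7), HPGD (4.80 and 3.30), PLAAT4 (4.44 and 2.89), the transcription factor GATA2 (3.14 and 2.62) and UPK1A. Those that fell included IL1A (-4.41 and -2.64), NT5E (-3.42 and -3.11), SNAI2 (-2.43 and -2.72), IL1B (-3.15 and -1.90), thrombospondin 1 (THBS1, -2.88 and -2.17) and TGFBI (-2.33 and -2.31). Genes that went opposite ways included FABP4 (-2.18 and 6.60), HAS3 (-3.22 and 1.97) and S100A8 (-1.72 and 3.26), and the cholesterol synthesis list fell in UC14 and rose in UC7.

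**Figure D4:**
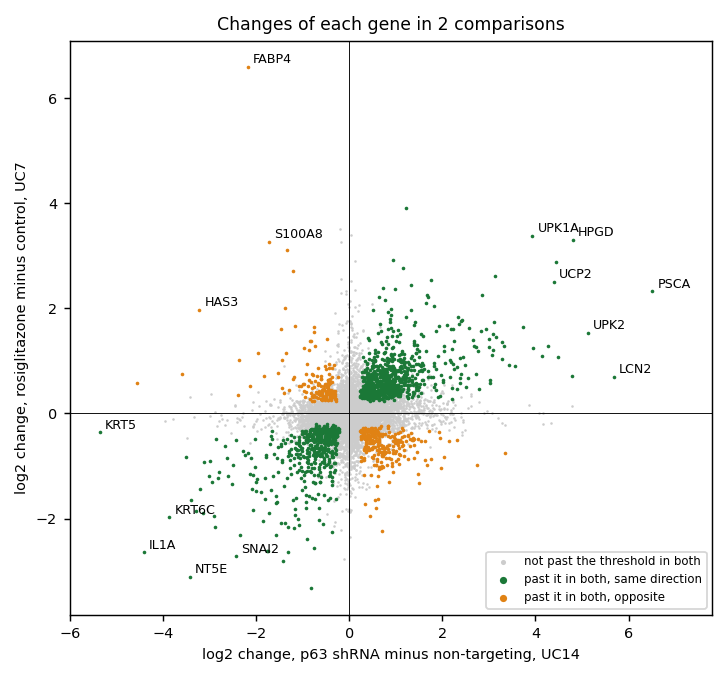
Log2 change of each of 11978 genes under p63 shRNA in UC14 (x axis) against that under rosiglitazone in UC7 (y axis); green points passed the threshold in both with the same direction, orange points in both with opposite directions, and grey points did not pass in both. The 1236 green points outnumber the 419 orange points, and FABP4, HAS3 and S100A8 lie at the upper left.

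Relative to the expected number, STAT3 siRNA shared fewer changes in the same direction with p63 shRNA and rosiglitazone (ratios 1.15 and 1.34) than those 2 shared (1.88). Opposite changes were more frequent with STAT3 siRNA (1.17 and 1.18 against 0.64). These ratios were not tested against each other. With p63 shRNA, 796 genes changed the same way (690.9 expected) and 818 in opposite ways (696.7 expected), with r = -0.0189 and rho = -0.0459. With rosiglitazone the counts were 508 (380.0 expected) and 449 (380.8 expected), with r = -0.00982 and rho = 0.0173. With p63 shRNA these counts were 412 (363.9 expected from the counts under that scaling) and 629 (558.1 expected) under median scaling, and with rosiglitazone 917 (767.3 expected) and 825 (767.4 expected) with array weights. Higher in all 3 comparisons were 117 genes (42.9 expected), and lower in all 3 were 104 (41.7 expected). The expected numbers treat calls as independent between comparisons, although all 3 use the same pooled spread of each gene. Both STAT3 siRNA pairs exceeded them in the same and in the opposite direction, so such an excess alone is no sign of a shared response. Genes at least 2-fold higher in each of the 3 were OAS1 (1.67, 1.29 and 2.26), the redox regulator TXNIP (2.09, 1.32 and 1.68), the lectin LGALS9 (3.10, 1.11 and 1.75) and ANXA9 (3.72, 1.06 and 1.64). Under both p63 shRNA and STAT3 siRNA, CDK6 (-3.51 and -1.43) and PTGS2 (-3.48 and -1.38) were among 22 genes at least 2-fold lower, and SLCO2A1 (-2.82 and -2.36) was among 16 under STAT3 siRNA and rosiglitazone. All these shared 2-fold calls rest on background-corrected values. Without that correction fewer genes reached 2-fold in each comparison.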

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

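Of the tests in this part, the interferon list in UC7 as a test of RNA interference and the correlation of the other pairs of comparisons were chosen only after the result was seen. Probes that carry no gene name here, 4321 of them past the same detection filter, stand outside the gene comparisons and also changed: 1478 passed an adjusted p of 0.05 under p63 shRNA in UC14, 478 under STAT3 siRNA in Scaber and 550 under rosiglitazone in UC7. Of these, 262, 71 and 109 changed at least 2-fold. What they measure was not analysed here.

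The interferon response list rose in all 3 comparisons with the preset correlation, though in Scaber 12 of 30 members were higher and 3 lower, with adjusted p = 0.291 with an estimated correlation. The list also rose in UC7 (camera adjusted p = 4.12e-09), where the labels name rosiglitazone and no RNA interference, so RNA interference does not account for that rise. The UC7 rise does not bear on the cause in UC14 and Scaber. Array scaling and background correction are argued against as the whole cause, because the highest camera adjusted p over 3 other scalings and the 3 comparisons was 0.000663. The UC14 median still moved from 1.44 to 0.895 without background correction and to 0.812 with the authors' values. Both of these scalings are quantile-normalized raw signal, so they are nearly the same check, and median scaling kept the background correction. For the knockdowns in UC14 and Scaber, a stronger innate response to the targeting than to the non-targeting RNA stays open, since 0 conditions with a further RNA against p63 or STAT3 were labelled, and it cannot be told apart from an effect of losing the target. An effect of each intervention on interferon signalling may be the reason in all 3, as a hypothesis untested here.

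The hypoxia and glycolysis list fell in all 3 comparisons, with medians of -0.526, -0.562 and -0.568. Scaling or background correction is argued against as the whole cause by a highest camera adjusted p of 7.59e-05 over the same other scalings, which are not all separate checks. An error in scaling bright probes is argued against too: among 10000 lists matched for brightness, the list's median lay at a percentile of at most 0.02 in the 3 comparisons. A difference in oxygen or nutrients between treated and control dishes, such as one from cell density, may also lower these genes and was not tested. A response to each intervention also stays open, as a hypothesis.

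The changes under p63 shRNA in UC14 and rosiglitazone in UC7 correlated across genes (r = 0.304). The members of the fixed lists, interferon genes included, do not by themselves make up the correlation, which was 0.297 across the 11678 genes outside them. Only 300 genes were left out, so this could change r little. Whether genes that change along with the lists carry the correlation was not tested. A probe or scaling effect common to all arrays is argued against by the other pairs of comparisons, whose higher r was -0.00982. A shared shift from a basal towards a luminal program may account for part of it, as a hypothesis. In UC7, 4 of 8 basal markers fell and 1 rose, and the list's camera adjusted p was 0.208 with an estimated correlation. KRT5, KRT14 and DSG3 were undetected in the UC7 controls. Line and intervention differ together, so no array tests such a shift.

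For each comparison the 6 arrays make 10 splits into 3 and 3, which cannot give a share under 0.05, and 1 of the 10, the real one, gave as many genes or lists. Genes called were 5351 in the real split and at most 33 in another in UC14, 3106 and 1 in Scaber, and 2934 and 0 in UC7. Lists called were 10 and at most 6 in UC14, 6 and 5 in Scaber, and 11 and 8 in UC7. The other splits mix treated and control arrays on both sides, so part of the real effect stays in the contrast and the rest enters the spread. They are no sample of unchanged arrays, and their low gene counts follow from that mixing.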

How the results depend on the processing

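All tests in this part were planned. Under the alternatives other than leaving out an array, 368 of the values that answer a comparison stayed on their side of the threshold or within 1.5 times, 13 lost their call, 20 moved further and 0 reversed. With 1 array left out, 295 stayed and 5 lost their call, all 5 of them the luminal difference between p63 shRNA and rosiglitazone. Of single genes and other lists, 4561 kept their side, 106 lost and 57 gained a call, and 0 reversed. With 1 array left out these were 2585, 133, 12 and 0. The cause was not tested for any value given here, except that fitting 6 arrays alone leaves a spread from those arrays only.

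Changed at least 2-fold were 493, 113 and 249 genes in UC14, Scaber and UC7 without background correction, and 482, 120 and 255 with the authors' values. Under median scaling 1262 genes were lower in UC14, 638 were higher in Scaber, 412 changed the same way under p63 shRNA and STAT3 siRNA (363.9 expected), and in UC7 1186 were higher and 1702 lower. In UC7, 4591 genes (2277 higher and 2314 lower) passed with its 6 arrays alone and 4894 (2453 and 2441) with array weights, where 917 and 825 went the same and opposite ways as under STAT3 siRNA (767.3 and 767.4 expected). The luminal difference between p63 shRNA and rosiglitazone had an adjusted p of 0.128 under median scaling, 0.0756 with a detection p under 0.05, 0.0508 with the replicate block, and 0.0288 to 0.0706 with 1 array left out, the basal difference 0.0608 with the mean of a gene's probes. With an estimated correlation 6, 3 and 5 lists shifted, with adjusted p of 0.0864 and 0.0554 (basal and luminal, UC14), 0.192 (basal, Scaber), 0.208 and 0.0752 (basal and luminal, UC7), 0.0697 and 0.109 (luminal, STAT3 siRNA against p63 shRNA and rosiglitazone) and 0.306 for both p63 shRNA and rosiglitazone differences.

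With replicate number as a block 5286, 2950 and 2747 genes passed, and the UC7 mesenchymal list had an adjusted p of 0.0704 (0.0724 with the title letter). Residuals of arrays of equal number correlated at -0.106 to 0.257. Arrays were most alike with their own number for Scaber replicates 2 and 3 and UC7 replicate 3, but not for the rest, so the numbers were not taken as pairs. For 2 rosiglitazone arrays number and title letter disagree, and the letter gave 2718 genes. A block by slide, the TP63 gene and differences between comparisons in fits of 6 arrays were not run. The 95th to 5th percentile ratio of signal was 10.3 to 14.1 in UC14 and 11.8 to 13.8 in Scaber, against 42.1 to 50.2 in UC7. Whether this limits the dim genes more in UC14 and Scaber was not tested.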

Other observations

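In the control arrays KRT5 had a mean log2 signal of 9.71 ± 0.18 (SD, n = 3) in UC14 and 10.94 ± 0.069 in Scaber, and was undetected in UC7. These levels are values within each line's arrays, whose background differs between lines, and they were not tested against each other.

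Single genes crossed the lines of their lists. FABP4, which rose 96.8-fold with rosiglitazone in UC7, fell by 2.18 in UC14 under p63 shRNA. The mRNA of its regulator PPARG differed by 0.08 there, and by 0.35 on another kept probe, without passing the threshold on either. TXNIP, LGALS9, ANXA9 and OAS1 rose at least 2-fold in all 3 lines with background-corrected values, where each was chosen after its values were seen. MKI67 rose by 0.86 in UC14 while CCNA2 and BUB1 fell, and it differed by -0.03 in Scaber, where 26 of 29 cell cycle genes fell.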
